A study of Mus musculus with 26 samples.

How the data were processed

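Total RNA from the entire heart of 13 mouse embryos at embryonic day 12.5 was measured on 26 oligonucleotide arrays. According to the labels the mouse line lacks the NK2-specific domain within Nkx2.5, a homeodomain transcription factor of the developing heart, and hearts were wild-type, heterozygous or null for it. There were 5 wild-type hearts (1, 2, 7, 9 and N1), 4 heterozygous hearts (5, 6, 12 and N2) and 4 null hearts (3, 4, 8 and N3). Each heart was run on an A array of 6584 probe sets and a B array of 6595 probe sets, and each array design includes 55 control probe sets. No heart number occurs in more than 1 genotype, and the labels give no litter, sex, date or pairing, so nothing shows whether hearts came from separate litters. P-values of single probe sets, of per-heart tests and of rotation tests measure only the spread between these hearts. The other list tests and Fisher's test take genes as their unit, and genes are not independent replicates.

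The deposited values were intensity on a linear scale, 1 value per probe set and array. The software that made them was not given in the sources used here. Negative values made up 10.1% to 29.5% of the values of an array, so a background or mismatch signal had been subtracted. The authors had scaled the arrays: on each of the 7 A and 9 B arrays without blank cells, the mean of the values between the 2 and 98 percentiles was 1500. Blank cells occurred on 6 A and 4 B arrays, in contiguous blocks of the table. The A arrays of wild-type heart 1, heterozygous heart 6 and heterozygous heart N2 lacked 81.3%, 71.8% and 62.5% of their values, and the B arrays of null heart 3, wild-type heart 9 and wild-type heart N1 lacked 80.6%, 71.4% and 71.4%. Blank cells were treated as missing, and each probe set was tested on the hearts that had a value.

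The noise of each table was the root mean square of its negative values, 443.5 for A and 686.4 for B. Values below 2 times the noise (887 and 1373) were raised to that floor before taking log2. A probe set was tested if at least 4 arrays exceeded the floor and each genotype had at least 2 values, and control probe sets were left out. This left 4494 probe sets, 2771 on A and 1723 on B. Of these, 3172 carried a single gene symbol in the platform annotation and covered 2733 genes; symbols were looked up by gene ID in the RefSeq table of assembly GRCm38.p6, which matched 5551 of 5560 IDs on A and 1993 of 2001 on B. Probe sets with several genes or none kept their own names, and 791 on A and 4512 on B had no gene. The annotation names 0 probe sets Nkx2-5, so Nkx2-5 expression was not analysed here. The number of arrays limits the precision of every value.

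Genotypes were compared with limma 3.58.1 in R 4.3.3, with 1 fit per array table to all 13 hearts, a variance trend, two-sided moderated tests and Benjamini-Hochberg adjustment over the probe sets of both tables. The threshold was an adjusted p of 0.05. Null against wild type, heterozygous against wild type, null against heterozygous, and null against the mean of the other 2 genotypes were tested. Gene lists were compared with all other genes by limma's competitive list test on the moderated statistics (1 probe set per gene, preset correlation 0.01, Benjamini-Hochberg over the lists), and again with a correlation estimated from the residuals. Negative estimates were set to 0, so for lists with an estimate under 0.01 the second test was the less strict one. Each list was also tested per heart, as the mean deviation of its genes in 2 genotypes, by an exact two-sided permutation test. Rotation tests (fry) used the 889 genes without blank cells, which left 11 lists. Lists with fewer than 3 tested genes were left out.

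The groups, tests, gene lists, naming rule and the alternative settings were fixed before the data were examined. The naming rule took the genes past the threshold, or else the 3 smallest p-values per direction that carried a symbol, and up to 4 members of each list by p-value. Within lists that did not pass, members named were later narrowed to those with an unadjusted p under 0.1. Several other steps departed from the plan. The plan scaled arrays again if trimmed means differed by over 5%; this cannot be judged on partly blank arrays, and read literally it would have chosen quantile scaling, so values as deposited were kept as the primary ones and quantile scaling served as an alternative. On the probe sets without blanks the arrays' trimmed means ranged from 0.924 to 1.06 (A) and 0.896 to 1.08 (B) times their median. The list test was run on precomputed statistics because of the blank cells, an Xist covariate was not run because Xist was blank on 3 A arrays and near the floor, cyclic loess was restricted to the tested probe sets after a first version failed on values tied at the floor, array weights were estimated on probe sets without blanks, and outlying samples were sought on measures restricted to those probe sets after blank arrays had stood out trivially.

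Alternatives covered scaling (quantile, common trimmed mean, cyclic loess), the floor, the filter, the transformation, the variance model, the hearts and arrays included, covariates, blocks, the threshold and the unit of counting. Of these, 4 were added after seeing the data: a robust noise estimate, heart-number lots (1 to 6, 7 to 12 and N) as a block, leaving out the 6 mostly blank arrays, and leaving out 3 B arrays with a low highest value. The analysis was tested on simulated data: of 4494 probe sets, 24.9%, 58.4% and 76.5% of those changed 1.5, 2 and 3 times between null and wild type were recovered, and 6.34% of calls were false. For heterozygous against wild type the shares were 21.1%, 57.2% and 75.3% with 6.50% false calls, and for null against heterozygous 16.9%, 52.9% and 74.2% with 5.80%. A list of 15 genes shifted by 0.2 on the log2 scale was found in 16 of 20 simulated draws of null against wild type over 2733 genes. Simulated values were drawn independently for each probe set and heart, without lots, array-scale effects or correlation between genes. The shares therefore describe the method under those conditions, and the rate of false calls in the real hearts may differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.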

Results

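The hearts of wild-type, heterozygous and null mouse embryos, in which the NK2-specific domain of the cardiac transcription factor Nkx2.5 was intact or deleted, were profiled at embryonic day 12.5 on an A and a B array each. Between 1232 and 6584 A probe sets and between 1278 and 6595 B probe sets had a value in a given heart. The share above the floor, over probe sets without blanks, was 46.8% to 51.9% on A arrays and 30.7% to 35.8% on B arrays. Spearman correlations between hearts were 0.913 to 0.973 on A and 0.851 to 0.972 on B. They averaged 0.941 within genotypes and 0.943 between them on A, and 0.925 and 0.927 on B.

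Null against wild-type hearts shows what accompanies loss of the domain from both alleles. The clearest difference was in an unnamed B probe set, w08218_s_at, which fell to 3673 ± 1220 (SD, n = 4) in null hearts from 9957 ± 826 (n = 5) in wild-type hearts. Its log2 difference was -1.49 ± 0.21 (SE) with an adjusted p of 0.0141 in limma, and the highest null heart (5328) lay below the lowest wild-type heart (8716). Among named genes, Tnni2, troponin I of fast skeletal muscle, averaged 1450 ± 576 (n = 4) in wild-type and 5321 ± 2673 (n = 4) in null hearts (log2 difference 1.83 ± 0.33), but its adjusted p was 0.113. Ntn1, the secreted guidance protein netrin 1, averaged 4167 ± 382 (n = 4) in wild-type and 2201 ± 294 (n = 4) in null hearts (log2 difference -0.93 ± 0.19, adjusted p = 0.206). In both genes no null heart overlapped a wild-type heart. Acta1, the alpha actin of skeletal muscle that embryonic heart also expresses, averaged 16047 ± 3852 (n = 4) in wild-type and 9783 ± 2764 (n = 4) in null hearts. Its log2 difference of -0.73 ± 0.21 was far from passing, with an adjusted p of 0.9999 in limma.

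**Figure D1:**
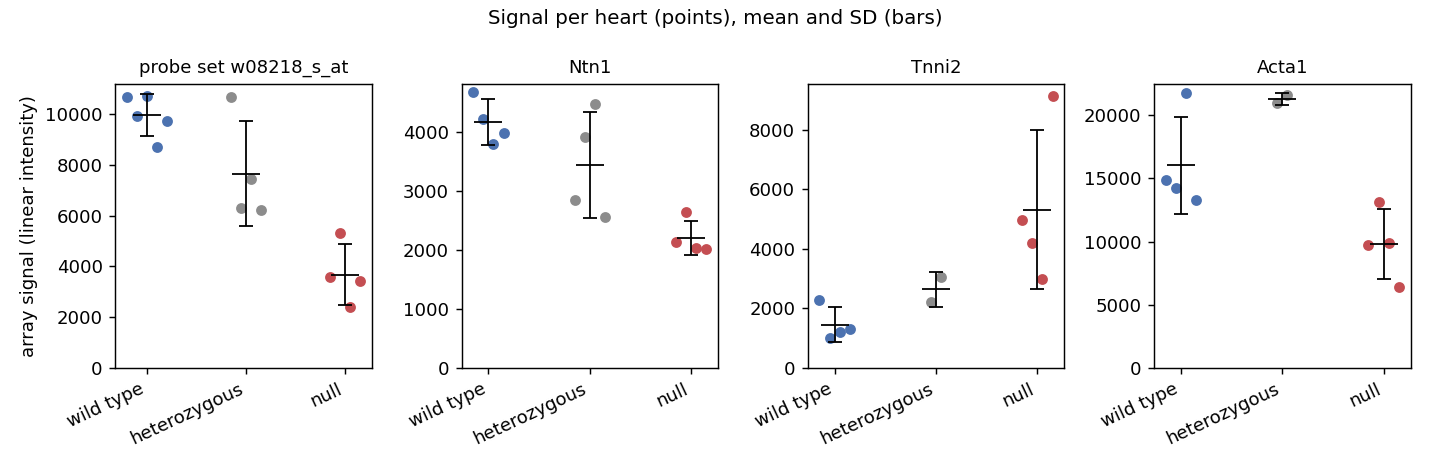
Array signal on the linear intensity scale (vertical axis) of probe set w08218_s_at, Ntn1, Tnni2 and Acta1 in each heart (points) by genotype, with the mean and SD (bars); hearts with a blank cell are absent. The w08218_s_at signal lay between 2391 and 5328 in null hearts and between 8716 and 10731 in wild-type hearts.

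In the limma fit w08218_s_at was the only one of 4494 probe sets called; 108 had an unadjusted p under 0.05, where chance gives 224.7. The call ended when wild-type heart 1 (adjusted p = 0.07), 7 (0.0603) or N1 (0.0536), or null heart 3 (0.0704) or N3 (0.092), was left out, although its log2 difference then stayed between -1.50 and -1.47. It also ended without the 3 N hearts (-1.48, adjusted p = 0.388), the 6 mostly blank arrays (-1.57, 0.127) or 3 B arrays of low range (-1.52, 0.0661). Over all leave-outs the number of called probe sets ranged from 0 to 3, the highest without wild-type heart 2, and 2 were called without heterozygous heart 5, 6 or 12. Without heterozygous heart 5 or 12 only 3066 probe sets could be tested. With heart-number lots as a block, a setting chosen after the data were seen, Ntn1 (-1.01, adjusted p = 0.0178), Tnni2 (1.67, 0.0273) and the unnamed A probe set aa217487_s_at (-1.84, 0.0273) passed beside it. The other named genes failed the correction without the block. They were Tmsb10 (0.42 ± 0.14, and 0.27 ± 0.16 by its second probe set), which binds actin monomers, Polm (0.53 ± 0.18), a DNA polymerase, Actn4 (-0.95 ± 0.25, but -0.36 ± 0.28 by its second probe set), a non-muscle actin crosslinker, and Slc1a5 (-0.47 ± 0.13), a neutral amino acid transporter (log2 differences). The means of Polm in wild-type hearts (2 of 4 above the floor, and 3 of 4 in null hearts), and of Slc1a5 (3 of 4) and this Actn4 probe set (2 of 4) in null hearts, lay under the floor, so these differences depend on values raised to it. The aa217487_s_at signal averaged 3726 ± 2093 (n = 5) in wild-type hearts and was below the floor in all 4 null hearts, so that the wild-type level was at least 3.8-fold higher (adjusted p = 0.061 without the block).

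Of the gene lists fixed in advance, 21 could be tested and 5 passed between null and wild-type hearts. The glycolysis and hypoxia list rose: 14 of 17 genes were higher in null hearts, with a mean log2 difference of 0.22 (adjusted p = 0.000214, and adjusted p = 0.0031 with an estimated correlation). Its members included the glycolytic enzymes Pkm (0.48 ± 0.17), Aldoa (0.75 ± 0.32) and Pgam1 (0.34 ± 0.17), and the prolyl hydroxylase P4ha1 (0.42 ± 0.23). Other probe sets were at 0.23 ± 0.19 for Pkm, and at 0.35 ± 0.13 and 0.46 ± 0.34 for Aldoa. The list's mean deviation was above every wild-type heart in all 4 null hearts. The endocardium and cushion list fell, with 13 of 15 genes lower and a mean of -0.20 (adjusted p = 0.00815, and adjusted p = 0.00659 with an estimated correlation). The estimated correlation did not make the test stricter for this list. Its mean deviation was below every wild-type heart only in null hearts 3 (-0.32) and 4 (-0.20), in which the extracellular matrix list was also low (-0.40 and -0.36), and stood at -0.0059 and 0.02 in null hearts 8 and N3. Its members included the endothelial receptors Kdr (-0.51 ± 0.32) and Tie1 (-0.29 ± 0.23), the endothelial cadherin Cdh5 (-0.30 ± 0.21) and the flow-responsive factor Klf2 (-0.39 ± 0.28). Tie1 was at 0.077 without the mostly blank arrays. The skeletal muscle list rose by a mean of 0.75 (adjusted p = 0.00184, and adjusted p = 0.00321 with an estimated correlation), but it held only 3 genes, Tnni2, Myog (0.36 ± 0.29) and Ckm (0.07 ± 0.39, and -0.44 ± 0.39 by its second probe set), and Tnni2 carried it. Over the alternatives its mean ranged from 0.14 to 0.98. The Tnni2 probe set is of a kind whose probes can match several members of a gene family, as are those given for Tmsb10 and Hba-x.

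Ribosomal protein genes were higher as deposited (26 of 29, mean 0.19, adjusted p = 4.1e-05) but lower after quantile scaling (-0.11, adjusted p = 0.0222) and not called after cyclic loess (-0.023), and the call was lost at adjusted p = 0.324 with an estimated correlation. Oxidative phosphorylation genes were also higher as deposited (36 of 41, mean 0.12, adjusted p = 0.000214) but stood at -0.021 after quantile scaling and 0.0087 after loess without passing, with adjusted p = 0.324 with an estimated correlation. Members of these lists included Rps15 (0.41 ± 0.18) and the cytochrome oxidase subunit Cox4i1 (0.60 ± 0.31). Both lists hold abundant transcripts, and the median difference of all probe sets above 15 on the log2 signal scale was 0.26 (160 probe sets). Per heart, in exact permutation tests, the glycolysis and hypoxia list differed by 0.21 (p = 0.0159, adjusted p = 0.333) and the endocardium and cushion list by -0.18 (p = 0.0952), so 1 of 21 lists had a p under 0.05. The smallest p that a list could have was 0.00794, too large for a single list to pass after adjustment over 21.

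**Figure D2:**
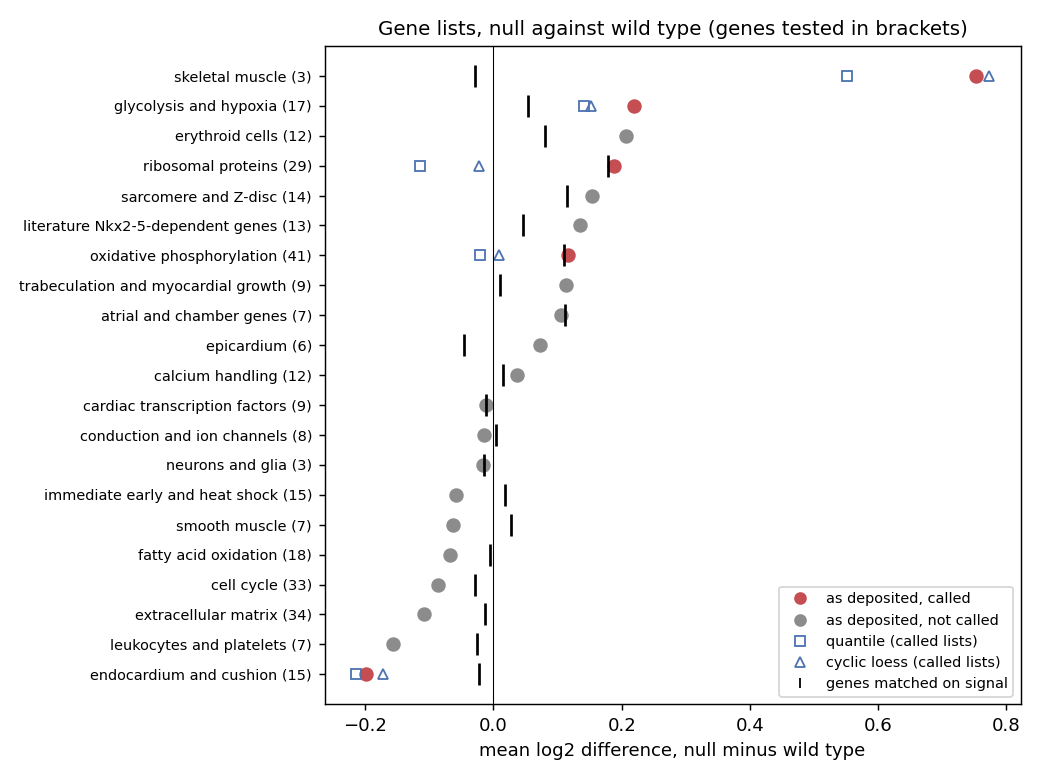
Mean log2 difference between null and wild-type hearts (horizontal axis) of the genes of each list (vertical axis, number tested in brackets) as deposited, after quantile scaling and after cyclic loess, with the mean of genes of similar signal (vertical ticks). Glycolysis and hypoxia genes were higher and endocardium and cushion genes lower under all 3 scalings, whereas ribosomal protein genes went from 0.19 to -0.11 and oxidative phosphorylation genes from 0.12 to -0.02 after quantile scaling.

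The endocardium and cushion, ribosomal and oxidative phosphorylation calls depended on a few hearts. The skeletal muscle call was kept in all 30 alternatives that could test it, and no left-out heart ended the glycolysis and hypoxia call. The endocardium and cushion call ended without wild-type heart 2 (adjusted p = 0.0574), null heart 3 (0.0913) or null heart 4 (0.0512), without the mostly blank arrays (-0.14, 0.133), without 3 B arrays of low range (-0.17, 0.0515) and with the robust noise estimate (-0.15, 0.0632). Leaving out null heart 4 also ended the ribosomal (0.13, adjusted p = 0.0512) and oxidative phosphorylation (0.077, 0.0834) calls, which stood against lower values after quantile scaling. Before such scaling, the oxidative phosphorylation mean was 0.18 without wild-type heart 2 and 0.077 without wild-type heart 7. The number of called lists was 9 without wild-type heart 1 and 2 without null heart 4. Without any filter, the glycolysis and hypoxia (0.15, adjusted p = 0.725) and endocardium and cushion (-0.09, 0.262) calls ended as well. The glycolysis and hypoxia mean was 0.14 after quantile scaling and 0.13 without the 3 B arrays of low range, and still called.

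The other 16 lists did not pass, with means from -0.16 to 0.21 and adjusted p-values of 0.0742 or more. Sarcomere and Z-disc genes averaged 0.15 (10 of 14 higher), with Acta1 at -0.73 ± 0.21, the cardiac LIM-domain gene Fhl2 at -0.69 ± 0.28, and the troponins Tnnc1 at 0.59 ± 0.26 and Tnni3 at 0.54 ± 0.25. Literature Nkx2-5-dependent genes averaged 0.14 (8 of 13 higher), including the potassium channel subunit Kcne1 (0.37 ± 0.15). By fry, on the 5 of these genes without blanks, the list went up on balance (adjusted p = 0.0319), the only one of 11 to pass. Atrial and chamber genes averaged 0.10 (Cited1 -0.56 ± 0.22), calcium handling 0.04 (Asph 0.34 ± 0.17), trabeculation and myocardial growth 0.11 (Vcan 0.34 ± 0.18), epicardium 0.07, and smooth muscle -0.06 (Tpm2 -0.75 ± 0.26). Extracellular matrix genes averaged -0.11 (24 of 34 lower, Dcn -0.46 ± 0.20), cell cycle genes -0.09 (28 of 33 lower), fatty acid oxidation -0.07 (Cpt1a -0.49 ± 0.21, Eci1 0.45 ± 0.20), immediate early and heat shock genes -0.06 (Dusp1 -0.28 ± 0.14), and leukocytes and platelets -0.16. Erythroid genes averaged 0.21, with Hba-x, an embryonic alpha-like globin, at 0.60 ± 0.24 and the haem enzyme Uros at -0.38 ± 0.21. The Hba-x probe set can match several members of its gene family. Null heart 8 stood apart in this list, with a mean deviation of 0.96 against -0.24 to 0.02 in the other null hearts, and so did wild-type heart 1 with 0.63 against -0.47 to 0.0033. Mean, median and test differed in sign for cardiac transcription factors (-0.01, with Hand2 at 0.62 ± 0.29 and Mef2d at -0.56 ± 0.27), conduction and ion channels (-0.02) and neurons and glia (-0.02). No liver gene was tested, and the lung and foregut and the sex-linked lists kept 1 gene each, Id2 (-0.05) and Xist (-0.17). When adjusted over the list alone, 2 genes passed, Acta1 (0.0473) and Tnni2 (0.000227), against 0 named genes over all genes tested. Their lists held only 14 and 3 tested genes, and the adjustment did not cover the 21 lists.

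Hearts numbered 7 to 12 and N differed from hearts 1 to 6 in more probe sets than genotypes did. With genotype in the model, 321 of 4494 probe sets were called between the 6 hearts numbered 1 to 6 and the other 7 hearts, 174 higher and 147 lower in the latter. The higher ones included Eln (1.23 ± 0.16), Mgp (1.54 ± 0.25), Lum (1.03 ± 0.18) and Eng (0.81 ± 0.14), and the lower ones Actb (-1.91 ± 0.23), the imprinted growth regulator Grb10 (-2.19 ± 0.27) and a probe set of the matrix gene Vcan (-0.97 ± 0.19). The extracellular matrix list was called higher in the later hearts (0.35, 27 of 34 genes higher, adjusted p = 9.0e-05, but adjusted p = 0.286 with an estimated correlation). The sarcomere and Z-disc list (-0.27) and the atrial and chamber list (-0.43) were called lower, also with adjusted p = 0.286 with an estimated correlation. The ribosomal protein and oxidative phosphorylation lists were called at -0.29 and -0.16 as deposited in this contrast, whose scaling alternatives were not run, and were lost at adjusted p = 0.286 with an estimated correlation as well. This grouping was chosen after the data were seen. Each lot held all 3 genotypes, and within lots 1 to 6, 7 to 12 and N the w08218_s_at difference was -1.24, -2.02 and -1.51. With lots as a block, 4 probe sets were called between null and wild-type hearts, w08218_s_at (-1.50, adjusted p = 0.0178), Ntn1 (-1.01, 0.0178), Tnni2 (1.67, 0.0273) and aa217487_s_at (-1.84, 0.0273).

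Heterozygous against wild-type hearts asks what loss of the domain from 1 allele accompanies. Complex I subunits Ndufa12 (0.63 ± 0.16) and Ndufa10 (0.87 ± 0.24) and the ubiquitin ligase Rnf26 (0.49 ± 0.14) had the smallest p-values among higher named genes. Fhl2 (-1.17 ± 0.31), the inhibitory G protein subunit Gnai1 (-0.52 ± 0.14) and Spats2 (-1.43 ± 0.41) had the smallest among lower ones. Ndufa10 was above the floor in 1 of 4 wild-type hearts, whose mean of 482 lay under it, and Gnai1 in 2 of 3 heterozygous hearts, whose mean of 856 did too, so these differences depend on values raised to it. Spats2 had values in 2 heterozygous hearts, 713 in heart 5, which is under the floor, and 4006 in heart 12, and its second probe set was at 0.13. Fhl2 averaged 1883 ± 55.5 (n = 2) against 4235 ± 145 (n = 2) in wild-type hearts, since most of its cells were blank in these genotypes. In limma 0 of 4494 probe sets passed, 152 had an unadjusted p under 0.05, and the smallest adjusted p was 0.224. With lots as a block, chosen after the data were seen, 1 unnamed probe set passed (-1.55, adjusted p = 0.0132). The w08218_s_at level was 7656 ± 2086 (n = 4), a log2 difference of -0.41 ± 0.21 that failed the correction.

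None of the 21 lists passed between heterozygous and wild-type hearts, by limma's list test or by fry (0 of 11), and 3 had an unadjusted p under 0.05. Leukocyte and platelet genes averaged -0.28 (6 of 7 lower, adjusted p = 0.0949), and oxidative phosphorylation genes 0.10 (27 of 41 higher, adjusted p = 0.0949). Glycolysis and hypoxia genes averaged -0.02 and endocardium and cushion genes -0.04; these were among 8 lists in which mean, median and test differed in sign. The number of called lists was 2 without wild-type heart 1, 3 without wild-type heart 2, and 1 without wild-type heart 7 or heterozygous heart 12. Without heterozygous heart 12 only 1707 genes could be tested. When adjusted over the list alone, Fhl2 (0.0479) and the endothelin receptor Ednrb (0.96 ± 0.34, 0.0411) passed. Their lists held only 14 and 3 tested genes, and the adjustment did not cover the 21 lists. Over all probe sets both failed in limma, with Fhl2 at an adjusted p of 0.981 and no higher probe set under 0.981. The log2 ratio of 3' to 5' Gapdh control signal on A arrays, a measure of RNA quality, was 0.002 in heterozygous and -0.15 in wild-type hearts (exact permutation p = 0.0159, adjusted p = 0.257 over 18 comparisons).

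Null against heterozygous hearts sets loss of 1 allele beside loss of both. Acta1 was lower in null hearts (-1.17 ± 0.25), and so were Efhd2 (-0.63 ± 0.16), a calcium-binding protein, and Ndufa10 (-0.95 ± 0.24). Pgam1 (0.69 ± 0.18), Hba-x (1.07 ± 0.29) and the ribosomal gene Rpl41 (1.75 ± 0.43) were higher. Ndufa10 was above the floor in 2 of 4 null hearts, whose mean of 804 lay under it, so its difference depends on values raised to it. Acta1, Hba-x and Rpl41 had values in only 2 heterozygous hearts, 5 and 12, and Efhd2 and Ndufa10 in 3. The heterozygous values were 62894 and 28403 for Hba-x and 52309 and 13574 for Rpl41, and both genes had values in 3 null hearts. Within hearts 1 to 6, the 1 lot with values of both genotypes for Hba-x and Rpl41, their differences were 0.61 and 0.81. All of these failed the correction over all probe sets, where limma called 0 of 4494, 260 had an unadjusted p under 0.05 and the smallest adjusted p was 0.129. When adjusted over the list alone, 4 genes passed, Acta1 (0.006), Pgam1 (0.0194), Hba-x (0.0353) and Atp2a2 (0.43 ± 0.13, 0.0419), the calcium pump of the sarcoplasmic reticulum. Their lists held 12 to 17 tested genes, and the adjustment did not cover the 21 lists. The unnamed probe set c80735_rc_at averaged 2785 ± 493 (n = 4) in null and 951 ± 117 (n = 2) in heterozygous hearts (1.52 ± 0.25), and passed only with lots as a block (1.62, adjusted p = 0.0108). It was also the probe set that passed between heterozygous and wild-type hearts with that block.

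Between null and heterozygous hearts 2 of 21 lists passed. Glycolysis and hypoxia genes rose (13 of 17 higher, mean 0.24, adjusted p = 0.0102, but adjusted p = 0.0564 with an estimated correlation). Extracellular matrix genes fell (25 of 34 lower, mean -0.19, adjusted p = 0.0102, but adjusted p = 0.571 with an estimated correlation). Both calls ended without heterozygous heart 5 (0.0762 for each) or 12 (0.108 for each), or null heart 4 (0.101 and 0.244). Leaving out heterozygous heart 5 or 12 also cut the tested genes from 2733 to 1707, because each genotype needed 2 values. The matrix call ended as well without null heart 3 (-0.11, 0.207). Without null heart 4 the matrix mean was -0.086, and without heterozygous heart 12 the glycolysis mean was 0.15. The matrix call ended after quantile scaling (-0.17, 0.085) and the glycolysis call without the N hearts (0.22, 0.0561). The matrix genes also differed between lots, and with lots as a block their mean was -0.22. The Gapdh 3' to 5' ratio on A arrays also differed between these genotypes (-0.14 in null and 0.002 in heterozygous hearts, exact permutation p = 0.0286, adjusted p = 0.257). The other 19 lists had means from -0.16 to 0.40 and adjusted p-values of 0.121 or more; 5 of them differed in sign between mean, median and test. By fry the Nkx2-5-dependent literature list went up (adjusted p = 0.00719), on Kcne1 (0.43 ± 0.16), Mef2c (0.40 ± 0.16), Actc1 (0.63 ± 0.58), Calr (0.38 ± 0.30) and Gja1 (0.06 ± 0.16). Per heart, the smallest exact permutation p of the 21 lists was 0.0571; 9 of them could not go under 0.05, because blanks left too few heterozygous hearts.

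**Figure D3:**
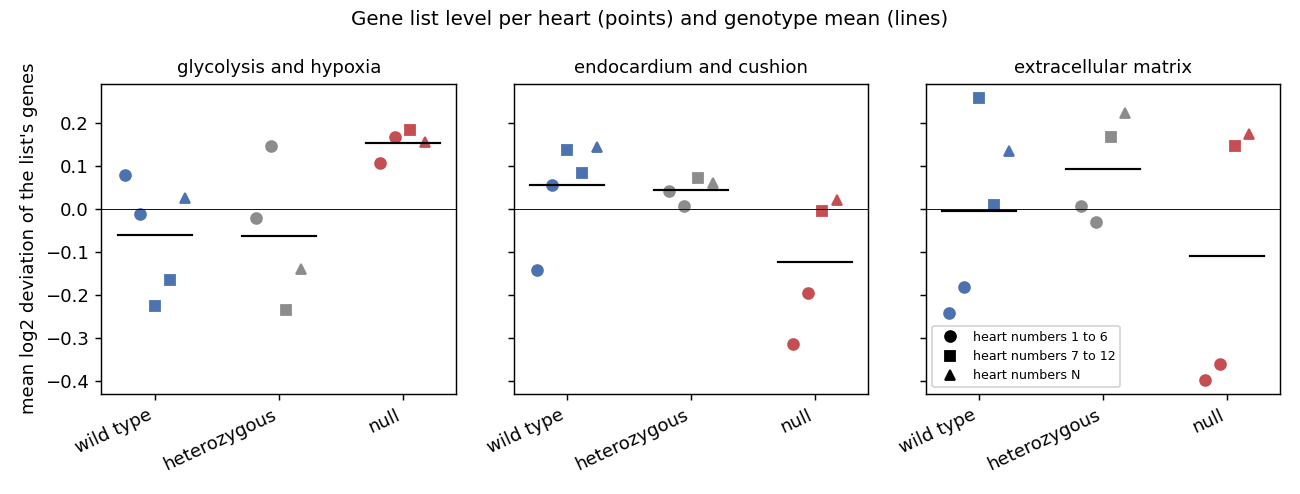
Mean log2 deviation of the genes of 3 lists from the average of their 3 genotype means (vertical axis) in each heart (points, shaped by heart-number lot) by genotype, with genotype means (lines). Each point averages only the genes with a value in that heart, such as 11 of 17 for glycolysis and hypoxia in wild-type heart 1. Glycolysis and hypoxia values of the 4 null hearts lay between 0.11 and 0.18 and those of the wild-type hearts between -0.23 and 0.08, while extracellular matrix values were lowest in null hearts 3 and 4.

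Null hearts were last compared with the mean of both other genotypes. The w08218_s_at signal was again the 1 probe set called (-1.29 ± 0.19, adjusted p = 0.0226), with 196 at an unadjusted p under 0.05; it was lost without wild-type heart 1, 2, 7 or N1 or null heart 3, 8 or N3, each leaving 0, and 2 were called without heterozygous heart 6. The count was also 0 after quantile scaling, after cyclic loess, without the N hearts, without the mostly blank arrays and without the 3 B arrays of low range. Tnni2 (1.37 ± 0.31), Acta1 (-0.95 ± 0.19), Ntn1 (-0.77 ± 0.16), Actn4 (-0.94 ± 0.22 by the probe set near the floor), Polm (0.55 ± 0.15) and the serotonin receptor gene Htr5a (0.43 ± 0.12) failed the correction. Polm and Htr5a averaged under the floor in wild-type and in heterozygous hearts, with Htr5a above it in 0 of 4 heterozygous hearts, so their differences depend on values raised to the floor. Of 21 lists 6 passed. Glycolysis and hypoxia (0.23, adjusted p = 0.000553) and skeletal muscle (0.57, 0.0228) rose, endocardium and cushion (-0.18, 0.00991) fell, and these 3 also passed with an estimated correlation. Extracellular matrix fell by this test (-0.15, 0.0073), but with adjusted p = 0.524 with an estimated correlation. Ribosomal proteins (0.15) and oxidative phosphorylation (0.07) were called as deposited but had negative means after quantile scaling (-0.13 and -0.068) and loess (-0.046 and -0.024), with adjusted p = 0.55 and adjusted p = 0.556 with an estimated correlation. Only 2 lists were called without null heart 3 and 1 without null heart 4.

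Across 2733 genes, which are not independent replicates, the null and heterozygous differences from the same wild-type hearts correlated at r = 0.29. Simulated groups without any change gave 0.44 (0.39 to 0.51), because both differences share the wild-type hearts. Permuted genotype labels averaged 0.43 (0.041 to 0.825), and 81 of 100 were at least as high as the real ones. The 0.29 thus lay below the whole simulated range but inside that of the permuted labels, which ignored the lots. With the wild-type hearts divided between the comparisons, in 10 ways, r averaged -0.15 (-0.44 to 0.044). These divisions also ignored the lots, so they do not show that the null and heterozygous differences ran in opposite directions. Near Nkx2-5 on chromosome 17, 0 of 58 tested genes within 300 genes on either side were called, as were 0 of 2675 elsewhere, and at an unadjusted limma p of 0.01 the numbers were 0 and 10 (Fisher's exact p = 1). With 0 genes called anywhere, the first count tests nothing, and the second rests on only 10 genes. Unnamed probe sets such as w08218_s_at could not enter, so no conclusion about the neighbourhood follows.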

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

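Tests chosen only after the results were seen were the within-lot and loess tests of w08218_s_at, the matched random lists and the splits within lots; the lots themselves were also defined after the data were seen. Among 106 groups of hearts, 5 held an outlying heart where about 1 in 20 groups, 5.3, is expected by chance. On the A array of null heart 8 the log2 ratio of 3' to 5' actin control signal was 0.19, against 0.41 to 0.44 in the other null hearts. On the B array of wild-type heart 1 the same ratio for Gapdh was 0.061, against -0.15 to -0.10 in the other wild-type hearts. The immediate early and heat shock list stood at 0.12 in heterozygous heart 12 and at -0.06 to -0.03 in the other heterozygous hearts. Polm log2 signal was 10.07 in heterozygous heart N2, with the other hearts of its genotype at the floor of 9.79. Slc1a5 log2 signal was 10.07 in null heart N3 and 9.79 to 9.82 in the other null hearts.

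Other splits of the same hearts show what chance gives together with the structure of the samples, since they were drawn without regard to lots. The counts of splits given here include the real grouping. For null against wild type, chance cannot be excluded for the 1 called probe set, since 14 of 100 splits called as many and the highest other called 320; nor for the 5 called lists, where 14 of 100 splits had as many and the highest other 11. A count of 0 is reached by every split and so tests nothing; this holds for heterozygous against wild type, with 0 probe sets and 0 lists (100 of 100 splits, highest others 54 and 9), and for the 0 probe sets of null against heterozygous (35 of 35, highest other 1). For the 2 lists of null against heterozygous chance cannot be excluded (11 of 35, highest other 5). For null against both other genotypes, 11 of 100 reshuffles reached the 1 probe set and 11 of 100 the 6 lists, with highest others of 80 and 10, so chance cannot be excluded. The split with 320 parted wild-type hearts 1 and 2 and null hearts 3 and 4 from all later hearts, so it followed the heart-number lots and points to a structure of the samples. Other splits with many calls also went with the lots, such as one with 167 that set wild-type hearts 7, 9 and N1 and null heart 8 apart.

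Splits that exchanged genotypes only within lots, with lots as a block, remove that structure. For null against wild type, 4 probe sets were called and 1 of 36 splits, the real one, had as many, the highest other having 0. That is the smallest share this test can give, and the tests were not adjusted for their number. Lots, block and splits were also chosen after the data were seen, so chance is less likely for this count but not excluded. For its 5 lists chance cannot be excluded (5 of 36 splits, highest other 7). For heterozygous against wild type chance cannot be excluded for the 1 probe set (9 of 36, highest other 6), and its 0 lists again test nothing (36 of 36, highest other 5). For null against heterozygous, 12 splits are too few for a share under 0.05; 2 of them reached the 1 probe set (highest other 2) and 3 the 3 lists (highest other 6).

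For the first pattern, the lower w08218_s_at signal in null hearts, the smallest difference within a heart-number lot was -1.24. After cyclic loess the difference was -1.42 (limma adjusted p = 0.0437). Both tests could hardly have come out otherwise, because the probe set was picked for its difference in these same hearts. Each lot also held null and wild-type hearts. The median null minus wild-type difference of probe sets at log2 signals of 12 to 13 was only -0.024. Both tests therefore add little on whether lots or a signal-dependent array scale contributed. Without the mostly blank arrays the w08218_s_at difference was -1.57 ± 0.28 (SE), against -1.49 ± 0.21 with them, which argues against those arrays. The call then ended (adjusted p = 0.127) because fewer hearts widened the error. Over the alternatives its adjusted p ranged from 0.00041 to 0.388. An effect of the deletion may underlie it, as a hypothesis, and the gene behind the probe set was not identified here. Chance was not excluded for its call in the splits that ignored lots (14 of 100). In the splits within lots, chosen after the data were seen, only the real one (1 of 36) reached the 4 calls that include it.

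The higher glycolysis and hypoxia, ribosomal and oxidative phosphorylation means in null hearts are the second pattern. For glycolysis and hypoxia, a share of 0.0014 of random lists matched on signal shifted as far, and with lots as a block the mean was 0.22, so neither a signal-dependent scale nor the lots account for it alone. Its lowest means per heart were in wild-type hearts 7 (-0.227) and 9 (-0.166) and heterozygous heart 12 (-0.236). These are the hearts whose B arrays had a low range. Without those 3 B arrays its mean was 0.13, still called, so these arrays may account for part of it. For ribosomal proteins the share was 0.385 and for oxidative phosphorylation 0.433, so a signal-dependent array scale may produce both shifts, which turned negative after quantile scaling. With lots as a block these means were 0.13 and 0.084, still called at the preset correlation, which argues against lots as their whole source, but without that block both calls were lost with an estimated correlation (adjusted p = 0.324 for each). A response of the null heart stays open and untested for all 3 lists, as does chance.

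The lower endocardium and cushion mean is the third pattern. A share of 0.0002 of signal-matched random lists shifted as far down, and with lots as a block the mean was -0.18, which argues against a signal-dependent scale and against lots as its whole source. Uncalled lists also had small shares, such as extracellular matrix (0.0024) and erythroid cells (0.0103). Their exact permutation p per heart was 0.556 and 0.484. The random genes were drawn singly, so a list whose genes vary together in a few hearts can stand out. The shares of this and the glycolysis and hypoxia list therefore speak to array scale and not to genotype. An effect of genotype may be one explanation, but chance is not excluded, and the call ended without wild-type heart 2 (adjusted p = 0.0574), null heart 3 (0.0913) or null heart 4 (0.0512). Only these null hearts lay below every wild-type heart.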

How the results depend on the processing

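The robust noise, the lot block and both sets of left-out arrays were chosen after seeing the data; the other alternatives were planned. Where no reason is given, the cause was not tested. Of 2381 values of single genes and lists under alternatives, 2253 kept direction and side of the threshold, 87 lost a call, 26 gained one and 15 changed sign. Among these single genes and probe sets only w08218_s_at was called at first, so for the others keeping the side means staying uncalled. The total therefore says little about how firm the calls were. The w08218_s_at call was kept in 24 of 32 alternatives (-1.69 to -1.31), the glycolysis and hypoxia call in 33 of 34 and the endocardium and cushion call in 27 of 34. No paired analysis was possible because heart numbers are not shared between genotypes. Signals under 887 (A) or 1373 (B) cannot be told from background.

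For null against wild type, 2 probe sets were called with the lower floor, asinh, robust variance, only both genotypes fitted, the erythroid covariate, adjusted p 0.10 or robust noise, 4 with the lot block, 1070 without a filter, and 0 without the N hearts, with one probe set per gene, without mostly blank arrays or without the low-range B arrays; leaving out 1 heart gave 0 to 3. For heterozygous against wild type the counts were 713 without a filter and 1 with the lot block, and for null against heterozygous 1 and 1. For null against both, 0 were called with quantile, loess, without N hearts, one probe set per gene, without mostly blank or low-range arrays, 2 with the lower floor or robust noise, 716 without a filter, and 0 to 2 leaving out 1 heart. Without a filter, values tied at the floor have almost no variance.

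Lists called, null against wild type, were 3 with loess, no filter or estimated correlation (2 to 9 leaving out 1 heart); heterozygous against wild type, 1 without a filter or with the erythroid covariate (0 to 3); null against heterozygous, 4 with the common trimmed mean, the higher floor, asinh or all probe sets, 1 without a filter, and 0 above the floor on all 13 arrays, with array weights or estimated correlation (0 to 3); null against both, 3 with the lower floor, no filter, array weights, estimated correlation or robust noise (1 to 8). The correlation of differences was 0.15 above the floor on all 13 arrays and 0.16 to 0.50 leaving out 1 heart, the highest without wild-type heart 2.

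Null against wild type, means turned negative for oxidative phosphorylation (quantile -0.021) and ribosomal proteins (quantile -0.11, loess -0.023), and against both for oxidative phosphorylation (-0.068, -0.024) and ribosomal proteins (-0.13, -0.046). Rpl23 was at -0.065 with quantile, Tie1 at 0.077 without mostly blank arrays, and Ckm at -0.048 with array weights, -0.082 without N hearts, -0.083 with the lot block and -0.22 to 0.62 leaving out 1 heart.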

Other observations

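A test of whether both arrays of a heart came from the same heart used the 129 genes on both designs. Among hearts of the same genotype, the own B array correlated best with the A array in 10 of 13 hearts, with r from 0.14 to 0.52 across the genes shared, which numbered as few as 16 on blank arrays. The other hearts were wild-type hearts 1 and 7 and heterozygous heart 6. Wild-type heart 7 shared 125 genes, and its A array had r = 0.32 with its own B array and 0.36 with that of another wild-type heart. A mismatch of its 2 arrays was not excluded, and the list tests use both.

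The highest intensity on a B array ranged from 36247 in wild-type heart 9 to 276817 in wild-type heart 1. It was also under 50000 in wild-type heart 7 (49132) and heterozygous heart 12 (46600).

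Xist, which marks the inactive X chromosome of female cells, was 0.59 lower on the log2 scale in null than in heterozygous hearts, which was not called (adjusted p = 0.774). The embryos' sex is not given by the labels and was not balanced in any test.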
